A study of Mus musculus with 29 samples.

How the data were processed

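Spinal cord RNA of 29 mouse libraries in 8 groups was measured by sequencing. Per the labels' protocols, mRNA was isolated on poly-T beads, primed with random hexamers and made into directional libraries with dUTP in the second strand. The mice were of either sex on a C57BL6 background, each 4 h library is a separate mouse, and littermates were assigned at random to ACC or Sham. Per the submitters' processing notes, reads were cleaned with fastp, aligned to GRCm38/mm10 with HISAT2 2.0.5 and counted with featureCounts 1.5.0-p3. The annotation release, the strand setting of the counting and the versions of fastp and of the authors' DESeq2 are not stated.

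Gene counts are as deposited by the authors, as whole numbers for 54532 genes in each library, of which 102 symbols belong to more than 1 gene identifier. The authors' normalized counts, a signal per gene and library, are the deposited counts divided by a size factor for each library, per the file headers and a check in which no value was off. The authors' log2 fold changes and their standard errors come from DESeq2, per the submitters' processing notes and the file headers. The deposited 4 h table gives Sham minus ACC and the deposited table of chemokine groups gives low minus high, and both were turned round for the text. The score of each gene in the authors' tables is the Wald statistic, per the file headers. The p-value and adjusted p-value columns are the authors' DESeq2 values as deposited, and the labels name an unadjusted p under 0.05 as the authors' threshold. Gene start, end and length are deposited annotation, per the file headers. The authors' worksheets of normalized values for chosen genes repeat the larger tables and were not analysed here. Per the labels, a further miR128KO ACC library (2) was corrupted, and library 1 of that group was left out by the study because it showed no change against Sham. Library 1 was left out here too, except where stated.

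Groups, comparisons, thresholds, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. All tests used the deposited counts. Counts were normalized with TMM, genes were kept by filterByExpr (minimum count 10), and quasi-likelihood F tests with robust dispersion were made in edgeR 4.0.16 under R 4.3.3. Adjusted p values follow Benjamini and Hochberg, with a threshold of 0.05. The SE of a log2 fold change is its absolute value divided by the square root of F. At 1 h, 17810 genes were tested (biological coefficient of variation 0.104, 4 residual degrees of freedom). The 4 h fit of ACC against Sham tested 17759 genes (0.134, 20 degrees of freedom). A fit of the 6 genotype and treatment groups tested 19581 genes with 16 degrees of freedom, for the ACC effect within each genotype, for a difference of that effect among the 3 genotypes, and for differences among Sham mice. Group levels are CPM with SD across mice, and log2 CPM used a prior count of 2.

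Same-numbered 1 h libraries come from the same mouse per the labels. Their deviations from the group means had correlations of -0.0118, -0.0487 and 0.0562 over 14132 genes. The unblocked fit was kept as the first fit and a fit with the mouse as a block was its alternative. That block called 32 higher and 44 lower genes, with 65 of the 78 first calls among them.

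The 36 gene lists cover chemokine ligands (CC; CXC, CX3C and XC) and chemokine receptors, GABA and glycine signalling, glutamate signalling, voltage-gated potassium channels, immediate early genes, cytokines and NF-kB feedback genes and heat shock proteins. They also cover responses to hypoxia, unfolded protein and integrated stress, p53, glucocorticoid and interferon, endothelial activation, reactive astrocytes and cholesterol synthesis. The cell markers are those of neurons, motor neurons, astrocytes, oligodendrocytes and their precursors, homeostatic microglia, endothelium, pericytes and smooth muscle, neutrophils, monocytes, lymphocytes, red blood cells, fibroblasts and meninges, ependyma, Schwann cells with dorsal root ganglion, and skeletal muscle. The last lists are rostral Hox genes, caudal Hox genes and mitochondrially encoded genes. Lists were tested with camera in limma 3.58.1 (preset correlation 0.01) on log2 CPM, adjusted over the 36, with camera at an estimated correlation as the alternative, and with fry.

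Genes are named by 3 rules. The first takes, for each comparison, the 10 largest positive and 10 largest negative fold changes past the threshold with a mean log2 CPM of at least 1 and the same direction in every animal pair (1 h) or genotype (4 h), without predicted or unnamed genes. The next always names Ccl2, Ccl3, Ccl4, Gad1, Gad2, Slc32a1, Slc6a5, Glra1 and Slc12a5, among others. The last takes from each list up to 4 members with the smallest adjusted p past the threshold, or the 2 with the highest mean CPM where none passed. The joint genotype tests name the 5 genes with the smallest adjusted p, and R3hdm1, Arpp21, Mir155hg and the microRNA genes are given to check the genotypes. A few genes that these rules cover are not reported here.

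The chemokine index was the mean log2 CPM of Ccl2, Ccl3 and Ccl4 in the 11 ACC libraries. It was compared with the scores of 10 lists by Pearson and Spearman correlation, with 100000 permutations, adjusted over the 10. The 1 h and 4 h fold changes were compared over the genes tested in both.

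The alternatives were DESeq2 1.42.0 (Wald tests, and likelihood ratio tests for the joint tests), its size factors inside edgeR, no filter beyond a total count above 0, each library left out in turn, and the mouse number as a block. At 4 h they also included genotype as a covariate and library 1 of the miR128KO ACC mice put back. Thresholds of an unadjusted p under 0.05 and of at least a 2-fold change were tried. For the index, they were residuals on genotype, DESeq2 size factors and the exclusion of the 2 libraries farthest from the median. For 1 h against 4 h, they were the block and a mean log2 CPM of at least 1. Chosen only after the data were seen were the exclusions of both libraries of 1 h animal 3, of 4 libraries with Alb above 25 CPM and of 2 WT Sham libraries with Gm28438 above 25 CPM. The unblocked fit of the 18 libraries of the 4 h block, the GABA and glycine list without Gabra2, and the 1 h against 4 h comparison without each 1 h library were also added then. So was a check of the labels of the WT Sham libraries, on genes chosen without the library in question.

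Recovery of changes was tested on simulated counts with the mean levels and dispersions of these libraries and 200 changed genes. The changed genes had a mean of at least 1 CPM. Libraries were drawn independently, without shared mice or an outlying library, so recovery in the real data may be lower. At 1 h, 62.7%, 83.6% and 98.5% of genes changed by 1.5, 2 and 4 times were recovered, with 5.2% false calls. At 4 h the shares were 85.1%, 98.5% and 100%, with 5.5% false calls. Tables were handled with Python 3.11, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9.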

Results

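Spinal cord RNA from mice was sequenced after aortic cross clamping (ACC), in which a clamp on the aorta interrupts the blood supply of the lower cord. The deposited data hold 29 libraries of poly-A selected RNA in 8 groups. At 1 h, thoracolumbar cord (n = 3) and cervical cord (n = 3) came from the same 3 wild-type (WT) mice. At 4 h, thoracolumbar cord came from ACC and Sham mice of 3 genotypes: WT (3 ACC, 3 Sham), a knockout of the microRNA miR-128 (miR128KO, 4 ACC, 4 Sham) and a knock-in of the microRNA miR-155 in motor neurons (miR155KI, 5 ACC, 4 Sham). Library 1 of the miR128KO ACC mice was left out, as in the study, since that cord had shown no change against Sham. That exclusion was made by outcome, and it left 11 ACC and 11 Sham libraries at 4 h.

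Total counts per library ran from 15596512 to 33056693, with a mean of 23.8 M (SD 4.48, n = 29). The means were 21.8 M (SD 5.38, n = 3) in cervical cord and 21.7 M (SD 4.31, n = 3) in thoracolumbar cord at 1 h. At 4 h they were 17.9 M (SD 0.671, n = 3) in WT ACC, 22.1 M (SD 1.76, n = 3) in WT Sham, 27.0 M (SD 5.52, n = 4) in miR128KO ACC and 24.1 M (SD 3.97, n = 4) in miR128KO Sham. The miR155KI libraries held 24.5 M (SD 2.41, n = 5) in ACC and 28.6 M (SD 2.73, n = 4) in Sham. Mitochondrial genes took 7.99% ± 0.716 (SD, n = 3) of the counts in cervical and 6.41% ± 0.166 in thoracolumbar cord at 1 h. At 4 h they took 5.10% ± 0.298 in ACC and 5.20% ± 0.510 in Sham (SD, n = 11 each). Levels below are given in CPM, counts scaled to a common library total. A gene without a count can lie at up to 3 counts, or 0.0908 to 0.192 CPM by library, which covers counting error only.

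The 1 h comparison addresses what early change separates the thoracolumbar cord, in the territory of the clamp, from the cervical cord that the study took as its spared control. Homeobox genes of body position gave the largest differences among the 17810 genes tested. Hoxc10 (ENSMUSG00000022484, GRCm38/mm10 chromosome 15, 102966796 to 102971893) was higher in thoracolumbar cord by 5.10 log2 units (SE 0.298, adjusted p = 0.000391), at 40.8 ± 3.41 CPM against 1.3 ± 0.875 (SD, n = 3 each). Hoxa10 (ENSMUSG00000000938, chromosome 6, 52231197 to 52240854) was higher by 4.08 (SE 0.142, adjusted p = 5.34e-11), at 42.3 ± 3.64 against 2.55 ± 0.592 CPM. Hoxd9 (2.58, SE 0.118) and Hoxa9 (1.80, SE 0.132) were higher as well, while Hoxc8 (-1.81, SE 0.0937, adjusted p = 1.73e-08) and Hoxc5 (-1.67, SE 0.164) were lower. The annotated span of Hoxc5 overlaps other genes of the Hoxc cluster, so the count of that gene is uncertain. Of 17 measured caudal Hox genes (groups 8 to 13), 11 were higher and 1 lower (15 and 1 adjusted over the list alone), with a camera adjusted p of 7.82e-27. The adjusted p was 0.145 with an estimated correlation. Of 10 rostral Hox genes (groups 4 to 6), 0 were higher and 2, Hoxc5 and Hoxc6 (-0.65, SE 0.104), were lower (0 and 2 adjusted over the list alone; camera adjusted p = 0.000767 for the list as lower, adjusted p = 0.514 with an estimated correlation). Hoxd11 stood at 3.08 ± 0.779 CPM in thoracolumbar and at 0.0217 ± 0.0375 in cervical cord, where it lay below the floor of 3 counts. With the animal as a block, Hoxc10 no longer passed (adjusted p = 0.0797). Over the 11 alternatives its adjusted p ran from 3.15e-152 to 0.0797.

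Several cholinergic motor neuron genes were lower in thoracolumbar than in cervical cord at 1 h. Slc5a7, the choline transporter of cholinergic terminals, differed by -0.89 log2 units (SE 0.0705, adjusted p = 3.14e-06), at 86.0 ± 3.27 against 160 ± 10.1 CPM (SD, n = 3 each). Chat, which makes acetylcholine, differed by -0.71 (SE 0.0916, adjusted p = 0.000653), at 26.9 ± 2.49 against 44.3 ± 3.64 CPM. The vesicular acetylcholine transporter Slc18a3, which lies inside the Chat gene, differed by -0.67 (SE 0.0845), and the intermediate filament gene Prph by -0.55 (SE 0.0688). Of 12 motor neuron markers, 0 were higher and 4 lower (0 and 8 adjusted over the list alone), with a camera adjusted p of 6.17e-12, against an adjusted p of 0.145 with an estimated correlation. Some mitochondrially encoded genes were lower too. Of 13 measured, 0 were higher and 4 lower (0 and 7 adjusted over the list alone; camera adjusted p = 1.33e-08, adjusted p = 0.404 with an estimated correlation). Among them, mt-Nd2 differed by -0.56 (SE 0.0724), mt-Nd5 by -0.43, mt-Cytb by -0.38 and mt-Nd1 by -0.47. Without cervical library 3 the adjusted p was 0.0698 for mt-Nd5 and 0.0768 for mt-Cytb, and without thoracolumbar library 2 it was 0.111 for mt-Nd1.

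The remaining genes named at 1 h have varied functions. The vesicular glutamate transporter Slc17a7 was higher by 2.65 (SE 0.278, adjusted p = 6.79e-05), at 5.04 ± 1.43 against 0.808 ± 0.161 CPM (SD, n = 3 each). Fgl2, a fibrinogen-like protein, was higher by 0.98 (SE 0.151, adjusted p = 0.00454). Higher values with a call that depended on single libraries were found for Igfbp5 (1.00, adjusted p = 0.0168, and 0.122 without cervical library 1), Slc2a4 (0.91, adjusted p = 0.0177, and 0.126 without thoracolumbar library 2), Uts2 (0.86, adjusted p = 0.00789, and 0.0672 without cervical library 3) and Ctxn3 (0.81, adjusted p = 0.0286, and 0.18 without cervical library 2). Ctxn3 also lost its call with the animal as a block (adjusted p = 0.054). Galnt15 (-1.42, SE 0.123), the galectin gene Lgals3 (-1.36, SE 0.183) and the calcium-binding S100a6 (-0.72, SE 0.110) were lower. So were Dmp1 (-0.78), Itpr3 (-0.71) and Calcb (-0.70), whose adjusted p reached 0.0556, 0.134 and 0.0762 when cervical library 3, thoracolumbar library 2 and cervical library 3 were left out in turn. The potassium channel gene Kcna1 (-0.43, adjusted p = 0.0286) and the filament gene Vim (-0.48, adjusted p = 0.0184) were lower, with adjusted p values of 0.171 and 0.0958 without cervical library 3.

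Immediate early genes, which respond within minutes to calcium entry and stress, and the heat shock gene Hspa1b differed between the 1 h animals. Fos stood at 317, 384 and 15.1 CPM in the thoracolumbar libraries of animals 1, 2 and 3, against 46.7, 34.3 and 24.1 CPM in their cervical libraries. Hspa1b stood at 384, 350 and 3.33 CPM against 14.8, 6.11 and 3.93. Over the 33 immediate early genes, the median difference of thoracolumbar minus cervical cord was 0.825, 1.06 and -0.343 log2 units in animals 1, 2 and 3. Over the 22 heat shock genes it was smaller, at 0.087, 0.113 and -0.163. None of Fos (2.77, adjusted p = 0.694), Jun (1.09, adjusted p = 0.727), Egr1 (1.72, adjusted p = 0.733) or Hspa1b (4.96, adjusted p = 0.612) passed. Without thoracolumbar library 3, Jun (1.47, adjusted p = 1.84e-05) and Egr1 (2.22, adjusted p = 1.62e-05) passed; over the 11 alternatives their adjusted p reached 0.96 and 0.965. Of the 33, 0 were higher and 0 lower (0 and 0 adjusted over the list alone). The camera adjusted p was 0.000222 for the list as higher, and the adjusted p was 0.939 with an estimated correlation. Of 22 heat shock genes, 0 were higher and 0 lower (0 and 0 adjusted over the list alone; camera adjusted p = 0.69), with values of 0.14 for Hspa8 and 0.05 for Hsp90aa1. Without thoracolumbar library 3, 88 genes were higher and 54 lower.

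**Figure D1:**
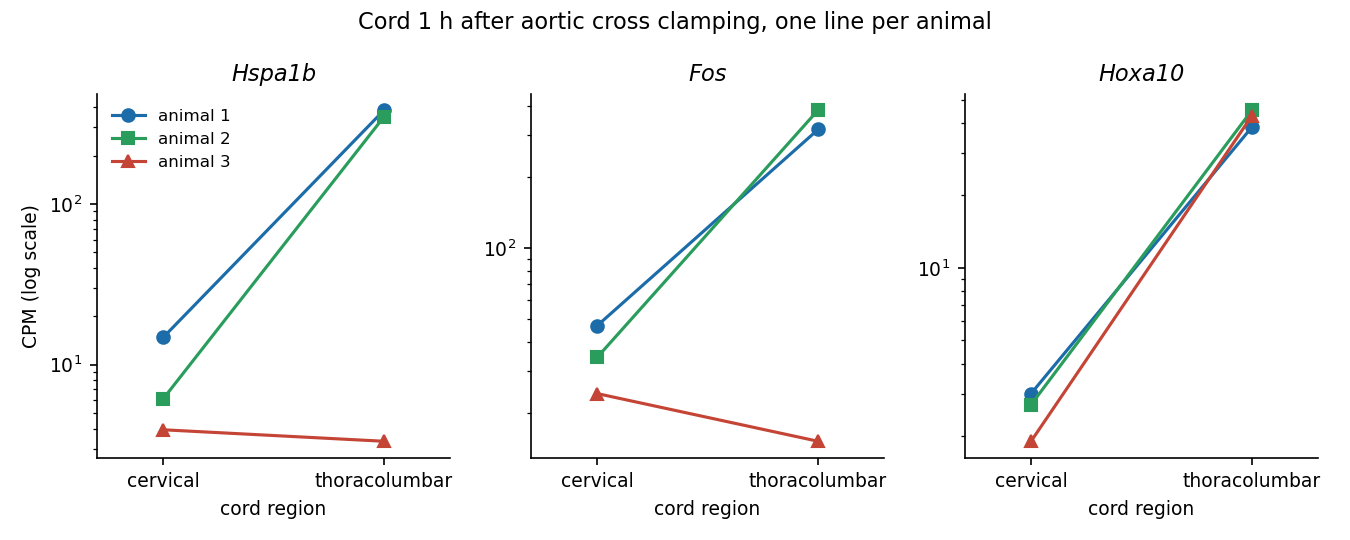
CPM of Hspa1b, Fos and Hoxa10 on a log scale in the cervical and thoracolumbar cord at 1 h, with a line for each of the 3 animals. Hspa1b reached 384 and 350 CPM in the thoracolumbar cord of animals 1 and 2 and 3.33 CPM in animal 3, whereas Hoxa10 was higher in the thoracolumbar cord of all 3.

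Chemokine and inhibitory signalling genes, the subjects of the series title, gave no call at 1 h. Ccl2 had a log2 difference of 1.13 (SE 0.428, adjusted p = 0.448), at 1.46 ± 0.661 against 0.680 ± 0.248 CPM (SD, n = 3 each). Ccl3 and Ccl4 did not pass the filter, which needs counts in as many libraries as a group holds, and stood at 3.67 ± 3.30 and 4.91 ± 4.31 CPM in thoracolumbar cord against 0.189 ± 0.203 and 0.161 ± 0.0711 in cervical cord. Thoracolumbar library 3 held 0 and 0.0476 CPM of them. In the authors' deposited table, Ccl3 had a log2 fold change of 4.27 and an adjusted p of 0.59. Of 9 measured CC chemokine ligands, 0 were higher and 0 lower (0 and 0 adjusted over the list alone; camera adjusted p = 0.759). Their median was -0.00 while their mean was 0.28 and the test pointed up; Ccl27a had a value of -0.12 and Ccl25 of -0.00. Of 33 genes of GABA and glycine signalling, 0 were higher and 0 lower (3 and 0 adjusted over the list alone). The camera adjusted p was 0.0253 for this list as higher, and the adjusted p was 0.939 with an estimated correlation. Gad1 and Gad2, which make GABA, had values of 0.15 (adjusted p = 0.69) and 0.25 (adjusted p = 0.221). The vesicular transporter Slc32a1 (0.10), the glycine transporter Slc6a5 (-0.03), the glycine receptor gene Glra1 (-0.44) and the chloride exporter Slc12a5 (0.09) did not pass either.

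In edgeR, 37 genes were higher and 41 lower in thoracolumbar cord at 1 h, and all 78 moved the same way in the 3 animals. Thoracolumbar and cervical values did not overlap for 2443 of the genes tested, where chance gives 10%, and for all 78 called genes. The 78 were called on these same values, so their shared direction and lack of overlap are not independent evidence. The authors' deposited table holds 62 higher and 64 lower genes by its adjusted p values. The 1 h data hold no Sham cord, so that a difference of region cannot be separated from an effect of the clamp. Leaving out cervical library 3 left 16 higher and 18 lower genes, leaving out thoracolumbar library 2 left 21 and 25, and leaving out cervical library 2 left 24 and 31.

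The 4 h comparison asks which genes respond to ischemia in the thoracolumbar cord, with chemokine ligands and inhibitory signalling as its stated subjects. Some C-C chemokine ligands rose from near 0 in ACC mice. Ccl4 (ENSMUSG00000018930, chromosome 11, 83662584 to 83664683) rose by 6.53 log2 units (SE 0.458, adjusted p = 1.29e-09), to 13.8 ± 7.31 CPM from 0.141 ± 0.106 (SD, n = 11 each). Ccl3 (ENSMUSG00000000982, chromosome 11, 83647844 to 83649355) rose by 6.06 (SE 0.383, adjusted p = 2.31e-10), to 18.3 ± 8.54 from 0.264 ± 0.152 CPM. Ccl2 (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453), a monocyte attractant, rose by 4.31 (SE 0.438, adjusted p = 1.8e-07), to 3.73 ± 2.16 from 0.177 ± 0.151 CPM. Sham values of these genes lay near the floor of 3 counts, which limits how exactly their folds are known. In the authors' deposited table the log2 fold changes were 6.60 for Ccl4, 6.10 for Ccl3 and 4.38 for Ccl2. Ccl9 rose by 1.53 (SE 0.183, adjusted p = 1.18e-06), to 8.63 ± 3.32 from 2.99 ± 0.671 CPM. Of 12 measured CC ligands, 4 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.000238, adjusted p = 0.0929 with an estimated correlation). The study chose Ccl2, Ccl3 and Ccl4 on these samples, so their part in the list is not independent evidence.

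**Figure D2:**
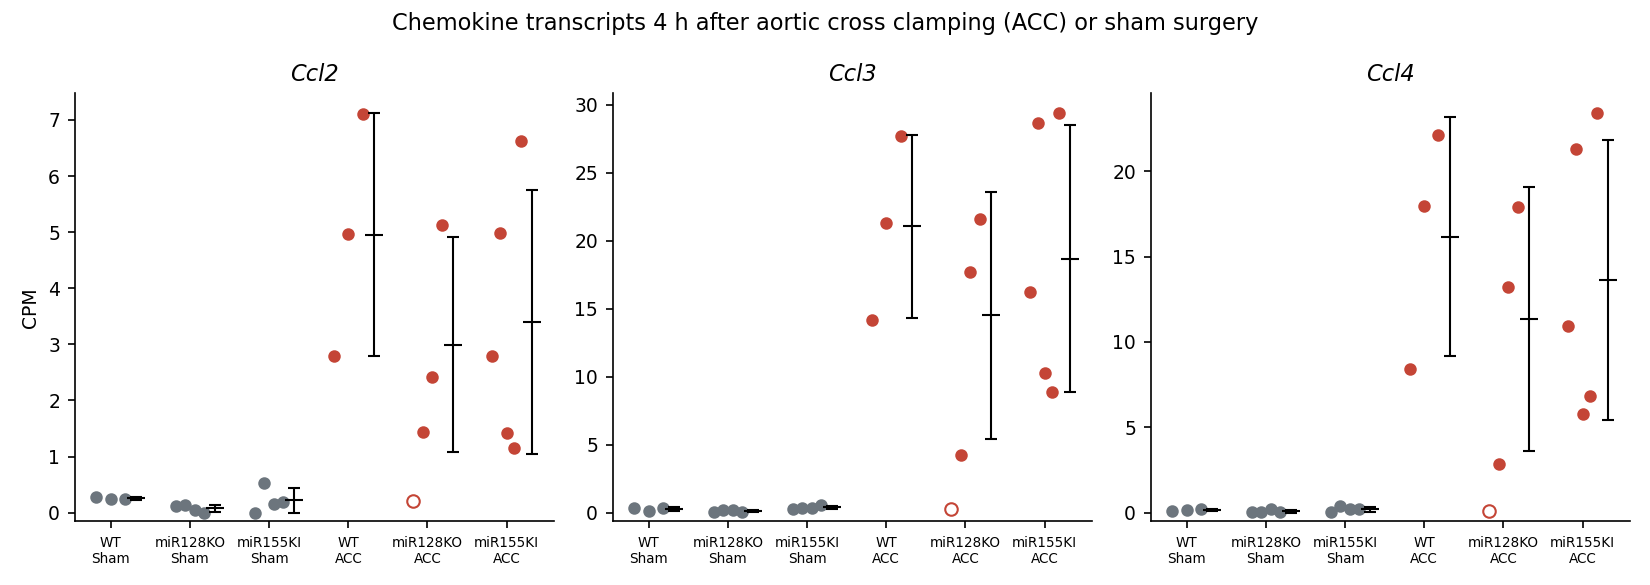
CPM of Ccl2, Ccl3 and Ccl4 at 4 h in each library of the 6 groups, with a black bar for the group mean and its SD; the open circle is the miR128KO ACC library that the study left out, which is not in the mean. ACC means were 3.73, 18.3 and 13.8 CPM over the 11 libraries, against 0.177, 0.264 and 0.141 CPM in Sham.

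Ligands of other chemokine classes and chemokine receptors gave fewer calls. Of 9 CXC, CX3C and XC ligands, 2 rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.438). The neutrophil attractant Cxcl1 rose by 2.88 log2 units (SE 0.365, adjusted p = 2.6e-06), to 2.38 ± 1.41 from 0.310 ± 0.162 CPM (SD, n = 11 each). Cxcl10 rose by 0.96 (adjusted p = 0.0456), a call lost in 16 of the 22 fits that left out a library (adjusted p = 0.086 without WT ACC library 2). Of 10 chemokine receptors, 3 rose and 0 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.834). Ccr1, a receptor for Ccl3, rose by 0.74 (SE 0.196; adjusted p from 0.00167 to 0.0704 over the 31 alternatives). The rise of the scavenger receptor Ackr3 (0.27, SE 0.0879) was lost in 4 of the 22 fits (adjusted p = 0.0707 without miR155KI ACC library 2).

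Of the genes of inhibitory transmission, 9 of 33 fell by small amounts and 1 rose. The glycine receptor subunit Glra3 fell by 0.46 log2 units (SE 0.0716, adjusted p = 2.85e-05), to 26.2 ± 3.20 from 36.0 ± 4.42 CPM (SD, n = 11 each). The glycine transporter Slc6a9 rose by 0.17 (SE 0.035, adjusted p = 0.000899). Adjusted over the list alone, 2 rose and 12 fell. The camera adjusted p was 0.00136 for the list as lower, and the adjusted p was 0.603 with an estimated correlation. The fry adjusted p was 0.0257 for a shift of the list in a single direction and 2.38e-07 for change in either direction. Change in either direction was not particular to this list. Its fry adjusted p was 4.8e-07 for glutamate signalling and 1.91e-17 for hypoxia genes, though 0.169 for neuron markers. Genes for making and loading the transmitters gave no call. Gad1 had a value of -0.05 (SE 0.0536, adjusted p = 0.605), at 196 ± 16.2 against 203 ± 20.9 CPM, and Gad2 of -0.08 (SE 0.0777, adjusted p = 0.547), with miR155KI Sham library 2 at 82 CPM. Slc32a1 (0.03, SE 0.0501), Slc6a5 (0.02, SE 0.0841), Glra1 (-0.07, SE 0.208) and Slc12a5 (-0.04, SE 0.0521) did not pass. Gabra2 had a value of -0.30 (SE 0.338, adjusted p = 0.619), and its level differed between the genotypes.

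**Figure D3:**
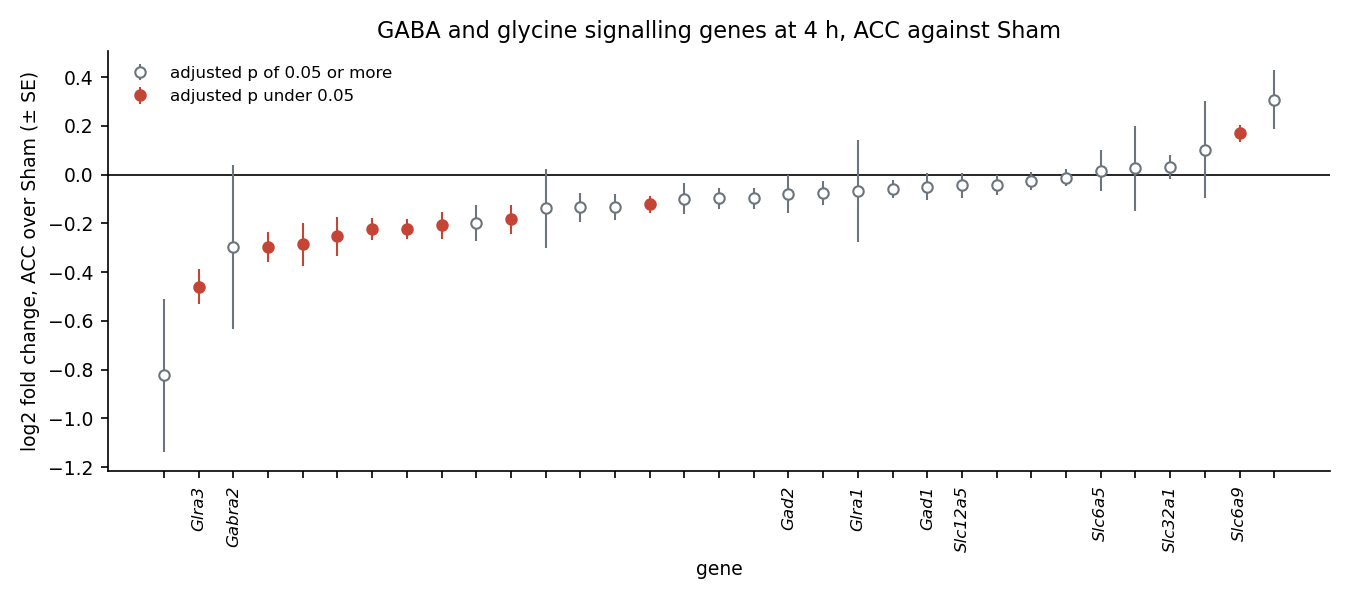
Log2 fold change of ACC against Sham at 4 h (y axis, with bars of 1 SE) for the 33 measured genes of GABA and glycine signalling (x axis, labelled where the text names the gene), from 11 ACC and 11 Sham libraries; filled points have an adjusted p under 0.05. Slc6a9 rose, 9 genes with Glra3 as the most changed fell, and the other 23 had no call.

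Heat shock and immediate early genes rose strongly. Hspa1b (ENSMUSG00000090877, chromosome 17, 34956436 to 34959238), a stress-induced chaperone, rose by 7.67 log2 units (SE 0.163, adjusted p = 6.16e-19), to 556.5 ± 121 from 2.72 ± 0.693 CPM (SD, n = 11 each). Hspa1a rose by 6.42 (SE 0.150), although its sequence is nearly that of Hspa1b, so that the counts of the pair are uncertain. The co-chaperone genes Dnajb1 (2.85, SE 0.0999) and Hsph1 (1.75, SE 0.0727) rose as well. Of 22 heat shock genes, 21 rose and 0 fell (22 and 0 adjusted over the list alone; camera adjusted p = 1.8e-38, adjusted p = 0.00135 with an estimated correlation). Among immediate early genes, Fosb rose by 4.54 (SE 0.248), Egr4 by 4.08 (SE 0.234), Egr1 by 3.81 (SE 0.18), Atf3 by 3.79 (SE 0.211), Arc by 3.27 (SE 0.140) and Jun by 2.44 (SE 0.113). Fos rose by 3.68 (SE 0.169, adjusted p = 1.73e-12), to 152 ± 38.2 from 11.9 ± 2.80 CPM. Of 33 immediate early genes, 28 rose and 0 fell (31 and 0 adjusted over the list alone; camera adjusted p = 4.05e-47, adjusted p = 0.00135 with an estimated correlation).

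Inflammatory and proteotoxic stress genes rose with them. Nfkbid (1.58, SE 0.163), Relb (0.89, SE 0.0991) and Nfkbiz (0.93, SE 0.108), regulators in the NF-kB pathway, rose, as did the microglial growth factor Csf1 (0.49, SE 0.0555). Of 25 cytokine and NF-kB feedback genes, 20 rose and 0 fell (21 and 0 adjusted over the list alone; camera adjusted p = 1.57e-14, adjusted p = 0.00784 with an estimated correlation). In the unfolded protein and integrated stress response, Chac1 rose by 1.61 (SE 0.0992), Ddit3 by 0.80 (SE 0.0731), the chaperone Hspa5 by 0.59 (SE 0.0551) and the transcription factor Xbp1 by 0.56 (SE 0.0469). Of its 24 genes, 17 rose and 0 fell (19 and 0 adjusted over the list alone; camera adjusted p = 7.49e-16, adjusted p = 0.00686 with an estimated correlation). Genes of fibrinolysis rose among the endothelial activation genes, with Plau at 2.51 (SE 0.25) and its receptor Plaur at 1.51 (SE 0.272), while the tissue factor gene F3 fell by 0.33 (SE 0.0563). Of 14 such genes, 7 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.000104, adjusted p = 0.075 with an estimated correlation). Of 18 reactive astrocyte genes, 6 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 2.65e-05, adjusted p = 0.159 with an estimated correlation), with Hspb1 (1.27), Sphk1 (0.80), the cytokine receptor Osmr (0.77) and Emp1 (0.63) as examples. Hspb1 is also among the 22 heat shock genes.

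Single genes of excitatory synapses and of potassium channels passed. Grin2a (-0.38, SE 0.0698), Grid1 (-0.35, SE 0.0613) and Grik3 (-0.35, SE 0.0707), which code for glutamate receptor subunits, fell, and the scaffold gene Homer1 rose by 0.78 (SE 0.106). Of 35 genes of glutamate signalling, 1 rose and 10 fell (1 and 14 adjusted over the list alone; camera adjusted p = 0.00491, adjusted p = 0.65 with an estimated correlation). Of 31 voltage-gated potassium channel genes, 3 rose and 6 fell (3 and 7 adjusted over the list alone; camera adjusted p = 0.172). Kcnd2 (-0.31, SE 0.045) and Kcns2 (-0.31, SE 0.0737) fell, and Kcnf1 (0.38, SE 0.0982) rose. The call of Kcns2 was lost with library 1 of the miR128KO ACC mice put back (adjusted p from 0.00105 to 0.0595 over the 31 alternatives). Of 15 neuron markers, 0 rose and 2 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.515), namely Syt1 (-0.27, SE 0.0579) and Elavl4 (-0.14, SE 0.0479). The call of Elavl4 was lost in 13 of the 22 fits that left out a library (adjusted p = 0.0859 without miR128KO ACC library 5). Of 12 motor neuron markers, 0 rose and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.313), with values of 0.10 for Ret and 0.11 for Slc5a7.

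Of 17 homeostatic microglia genes, 6 fell and 1 rose. P2ry12, the purine receptor of resting microglia, fell by 0.78 log2 units (SE 0.101, adjusted p = 2.87e-06), to 14.5 ± 2.61 from 25 ± 4.59 CPM (SD, n = 11 each). Tmem119 fell by 0.79 (SE 0.144, adjusted p = 0.000458), to 13.2 ± 4.00 from 22.7 ± 3.97 CPM, Selplg by 0.53 (SE 0.0811) and Siglech by 0.32 (SE 0.0822; adjusted p from 0.00097 to 0.0664 over the 31 alternatives). The list had a camera adjusted p of 0.00536 (adjusted p = 0.603 with an estimated correlation), and 1 rose and 6 fell adjusted over the list alone. The gene that rose was Fcrls (0.34, SE 0.0972), named after its value was seen. Of 12 astrocyte markers, 1 rose and 3 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.138). The transcription factor gene Sox9 rose by 0.60 (SE 0.0804), and the growth factor receptor Fgfr3 (-0.26, SE 0.0362) and the gap junction genes Gjb6 (-0.33, SE 0.0706) and Gja1 (-0.17, SE 0.0419) fell.

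Among the genes that fell most in ACC were Tekt4, a tektin of cilia (-1.17, SE 0.169, adjusted p = 1.37e-05), Tfap4 (-0.94, SE 0.138), the Wnt receptor Fzd2 (-0.93, SE 0.156), the noncoding RNA AI480526 (-0.91, SE 0.115), the kinase subunit Pik3cg (-0.88, SE 0.123), the uncoupling protein Ucp3 (-0.87, SE 0.125) and the neuromedin receptor Nmur2 (-0.82, SE 0.171). The call of Islr (-1.08, SE 0.339, adjusted p = 0.0323) was lost in 8 of the 22 fits that left out a library (adjusted p = 0.0632 without miR155KI Sham library 2). That of Cd177 (-1.07, SE 0.330, adjusted p = 0.0281) was lost without miR128KO Sham library 1 (adjusted p = 0.0545). With library 1 of the miR128KO ACC mice put back, the calls of Nmur2, Islr and Cd177 were all lost, and over the 31 alternatives their adjusted p reached 0.0629, 0.173 and 0.249. The liver gene Hpx rose by 3.72 (SE 1.06, adjusted p = 0.0196), with 78.6 CPM in miR155KI ACC library 5, and it did not pass without that library (log2 2.00, adjusted p = 0.109) or with genotype as a covariate (adjusted p = 0.0909). Over the 31 alternatives, its adjusted p ran from 0.000841 to 0.563. Albumin (Alb), another liver transcript, reached 393 CPM in the same library.

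In edgeR, 1664 genes rose and 1250 fell in ACC at 4 h, 16.4% of the 17759 tested, with median changes of 0.291 and 0.258 log2 units in size. Of the 2914, 142 rose and 16 fell by at least 2-fold, and 2869 had the same sign within all 3 genotypes. The calls were made on the same libraries, so this shared sign is not independent evidence. ACC and Sham libraries did not overlap for 220 of the 2914. The authors' deposited table holds 2025 higher and 1369 lower genes by its adjusted p values. Library 1 of the miR128KO ACC mice, put back, gave 1439 and 998. Without the 4 libraries with more than 25 CPM of Alb, 1167 genes rose and 824 fell, which is an exclusion chosen after the data were seen.

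Within each genotype, the ACC effect asks whether the response holds across mice that differ in the studied microRNAs. The chemokine genes rose in all 3 genotypes. Ccl4 rose by 6.72 in WT, 7.19 in miR128KO and 6.06 in miR155KI mice, Ccl3 by 6.2, 6.81 and 5.59, and Ccl2 by 4.27, 5.11 and 3.9 log2 units. In a fit of the 6 groups over 19581 genes, 281 genes rose and 57 fell in WT (3 ACC, 3 Sham), 406 and 129 in miR128KO (3 ACC, 4 Sham), and 645 and 259 in miR155KI mice (5 ACC, 4 Sham). With library 1 put back, the miR128KO count was 151 in place of 535. Single libraries moved these counts by over 1.5 times. The WT count of 338 was 172 without ACC library 2, 170 without ACC library 3, 170 without Sham library 1, 185 without Sham library 2 and 188 without Sham library 3. The miR128KO count was 289 without ACC library 3, 325 without ACC library 5 and 338 without Sham library 4, and the miR155KI count of 904 was 597 without ACC library 5 and 566 without Sham library 1.

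A difference of the ACC effect among the genotypes was called for 0 genes by edgeR (618 at an unadjusted p under 0.05) and for 1 by DESeq2 (856 unadjusted). The 5 genes with the smallest p were Epb41l4aos, Polr3d, Gm28438, Gm22009 and Rp9, each with an adjusted p of 0.992. Without WT Sham library 1, edgeR called 2 genes.

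The genotypes were first checked at the altered microRNA loci. R3hdm1 and Arpp21, which host the copies of miR-128, stood at 73.2 ± 9.74 and 41.3 ± 7.28 CPM in miR128KO Sham (SD, n = 4) against 71.6 ± 4.71 and 33.1 ± 2.22 in WT Sham (SD, n = 3). Mature microRNAs are not captured in poly-A libraries, and the host genes do not show whether miR-128 itself was removed. Mir128-2 and Mir155 had no counts in any 4 h library. The miR-155 host transcript Mir155hg stood at 0.775 ± 0.450 CPM in miR155KI Sham (SD, n = 4) and 1.29 ± 0.350 in miR155KI ACC (SD, n = 5), against 0.166 ± 0.121 in WT Sham and 0.167 ± 0.0551 in WT ACC (SD, n = 3 each). It stood at 0.111 ± 0.0886 in miR128KO Sham (SD, n = 4) and 0.137 ± 0.0222 in miR128KO ACC (SD, n = 3).

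A comparison of Sham mice asks how the genotypes differ without ischemia, and 17 genes passed its joint test. The adjusted p values given here are of the joint test. Against WT Sham alone, 0 genes passed for miR128KO (smallest adjusted p = 0.062) and 0 for miR155KI Sham (0.0608). Between miR155KI and miR128KO Sham, 29 passed. The mitochondrial transfer RNA mt-Tr differed by -4.51 log2 units in miR128KO and 1.17 in miR155KI Sham against WT Sham (adjusted p = 0.00177). Its mean was 0.0218 CPM in miR128KO Sham, below the floor of 3 counts, and 0.600 CPM in WT Sham. The pseudogene Gm28438 (adjusted p = 0.00373) stood at 65.8 ± 7.34 CPM in miR128KO (SD, n = 4), 33.4 ± 26.4 in WT (SD, n = 3) and 3.37 ± 0.807 in miR155KI Sham (SD, n = 4). Pdxk, the kinase of vitamin B6, stood at 157 ± 13, 123 ± 16.2 and 106 ± 11.7 CPM (adjusted p = 0.00475). Tspan14, a tetraspanin, stood at 40.6 ± 2.13, 36.9 ± 1.40 and 26.4 ± 1.42 CPM in the same order (adjusted p = 0.00475). Gm10591 had no counts in miR128KO Sham, 0.3 ± 0.299 CPM in WT Sham and 1.48 ± 0.83 in miR155KI Sham (adjusted p = 0.00475). Ide, mt-Nd3, Gabra2 and Mir155hg were also among the 17 and are named after their values were seen. The inhibitory receptor gene Gabra2 (adjusted p = 0.0139) ran from 118 to 176 CPM in miR128KO, from 47.8 to 50 in miR155KI and from 50.1 to 162 in WT Sham. Within WT mice, Gabra2 was lower in ACC than in Sham by 1.08 log2 units (log2 fold change -1.08, SE 0.264, adjusted p = 0.0464), against values of 0.08 (SE 0.238) in miR128KO and 0.24 (SE 0.216) in miR155KI mice. DESeq2 called 82 genes in the joint test. In edgeR, the count was 11, 7, 9 and 6 without miR128KO Sham libraries 1, 2, 3 and 4, and 9 without miR155KI Sham library 3.

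**Figure D4:**
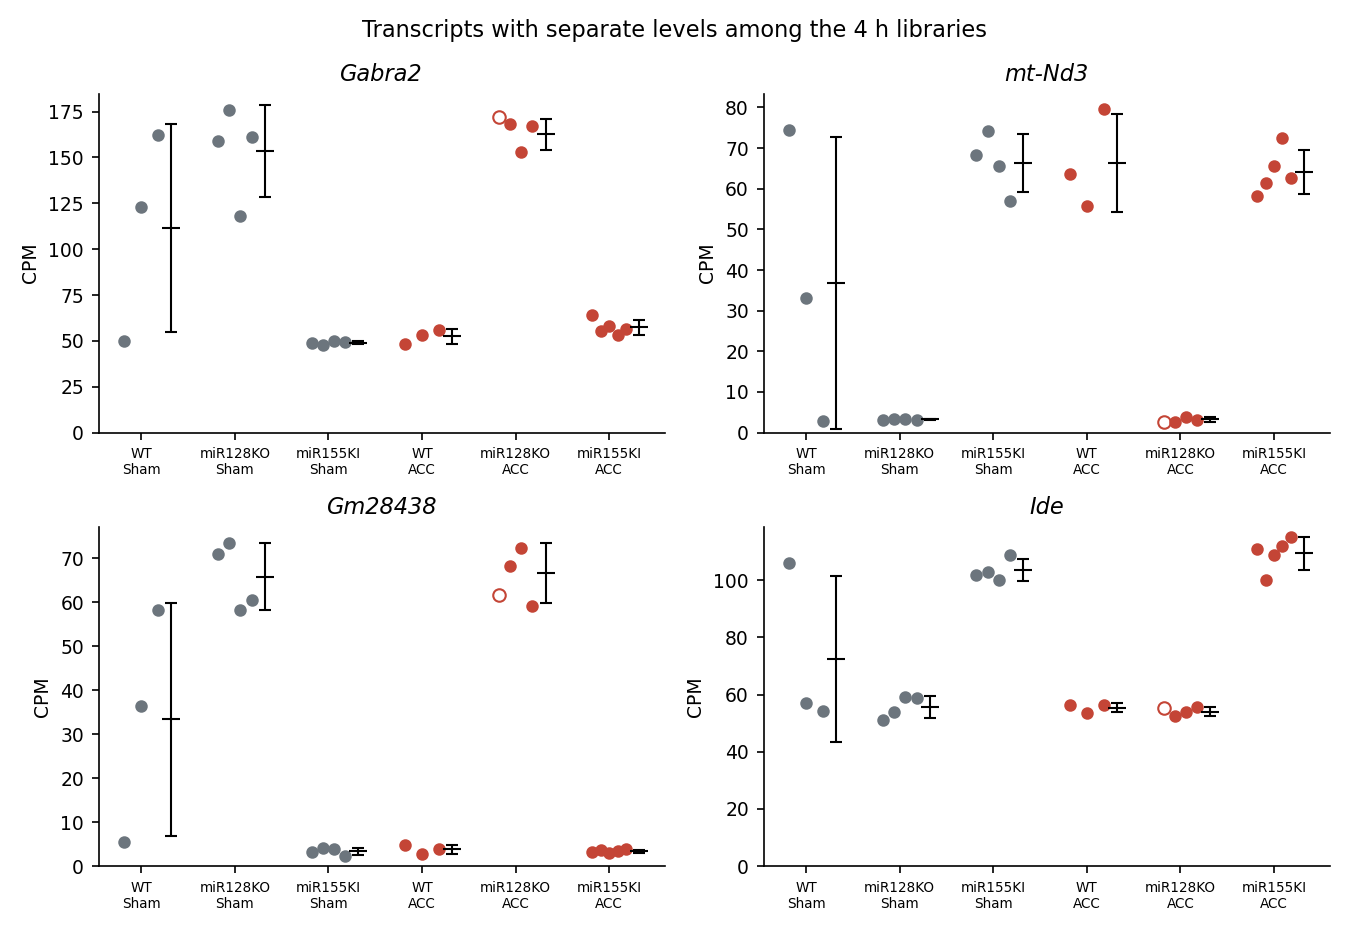
CPM of Gabra2, mt-Nd3, Gm28438 and Ide at 4 h in each library of the 6 groups, with the mean and SD per group; the open circle is the miR128KO ACC library that the study left out. In WT Sham the libraries spread over the levels of both other genotypes, with Gabra2 from 50.1 to 162 CPM and mt-Nd3 from 2.92 to 74.4 CPM.

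How far the 1 h regional contrast and the 4 h ACC contrast moved the same genes was compared over 17383 genes. Of these, 1 gene was higher in both, where independent lists would share 3.47, and 0 were lower in both, where independent lists would share 2.94. Another 11 genes were called in opposite directions, where independent lists would share 6.49. The fold changes had a Pearson r of 0.0926 (jackknife SE 0.0922 over the 6 libraries of 1 h) and a Spearman rho of -0.0266 across genes, which are not independent replicates. Over genes of at least 1 log2 CPM, the r was 0.187. Over all genes, it ran from 0.0518 without thoracolumbar library 1 to 0.167 without thoracolumbar library 3.

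The last comparison asks whether ACC mice with more of the 3 chemokines differ in other genes. An index, the mean log2 CPM of Ccl2, Ccl3 and Ccl4, ran from 1.41 to 4.08 over the 11 ACC libraries. With the score of the cytokine and NF-kB feedback genes it had an r of 0.696 (permutation p = 0.0199, adjusted p = 0.199) and a rho of 0.7 (permutation p = 0.0204, adjusted p = 0.204), which did not pass over the 10 lists computed. Without the 2 libraries farthest from the median index, this r was 0.851 (permutation p = 0.00677, adjusted p = 0.0677) and the rho was 0.867 (permutation p = 0.00442, adjusted p = 0.0442), of which the rho passed. For GABA and glycine signalling, the r was -0.101 (permutation p = 0.767, adjusted p = 0.853) and the rho 0.182 (permutation p = 0.597, adjusted p = 0.936), and r was -0.119 without the 2 farthest libraries. The other 8 lists had r values from -0.198 to 0.551. With library 1 of the miR128KO ACC mice put back, 3 lists passed by r. By rho, the cytokine and NF-kB feedback genes passed (adjusted p = 0.0489). The immediate early genes (adjusted p = 0.278) and endothelial activation genes (adjusted p = 0.136) did not. The authors' deposited table compares 3 mice with high and 3 with low levels of Ccl2, Ccl3 and Ccl4, groups that were chosen by those genes, so their own difference is not independent evidence. It holds 53 higher and 4 lower genes by adjusted p in the high group, with Plek at 0.88 and Gad1 at -0.04 log2 units. In that table Alb stood at 5.71 (adjusted p = 0.0553).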

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

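The tests of animal 3, of the gene levels that part the genotypes, of Gabra2 within WT and of the liver and adipocyte transcripts were chosen only after those results were seen; the counts of other splits were fixed earlier.

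In groups of 4 or more mice, a library stood apart where its gap to the nearest other mouse took an unusually large part of the group range (Dixon's 95% bound). This was met in 10 of 90 tests, and chance alone meets it in about 1 in 20 groups. In miR128KO Sham these were Ccl4 in library 3 (0.206 CPM, next 0.0433), Egr4 in library 2 (3.52, next 1.69), Islr in library 3 (10.9, next 3.85) and Slc6a5 in library 1 (395, next 329). In miR155KI ACC they were Hpx (78.6, next 15.7) and Cd177 (4.24, next 1.83) in library 5 and Slc32a1 in library 3 (188, next 165). In miR155KI Sham they were Ccl3 in library 4 (0.569, next 0.343), Tmem119 in library 4 (lowest at 23.2, next 25.2) and Gad2 in library 2 (lowest at 82, next 130). The Ccl4 value lies near the floor of 3 counts (0.156 CPM in that library), while the Ccl3 value lies well above it (0.116 CPM). In library 1 of the miR128KO ACC mice, outside the comparisons, the sensory neuron gene Scn10a stood at 3.73 CPM against at most 0.156 in any Sham library. In that library, 0 of the 10 most raised named genes of 4 h lay above every Sham library.

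Other splits of the same libraries show where chance can be excluded. For 4 h ACC against Sham, the real split gave 2914 genes and the highest of the others 828, and 1 of 100 drawn splits, the real one, gave as many. Within miR128KO the real split gave 535 and the highest other 133 (1 of 35), and within miR155KI 904 and 370 (1 of 100). Among Sham genotypes it gave 17 and 8 (1 of 60). Chance can be excluded within miR155KI. Among Sham genotypes it is excluded only with all Sham libraries in. Without miR128KO Sham library 2 or 4 the real count was 7 or 6, under the highest other of 8. The splits were not redrawn without those libraries. The pooled and miR128KO splits lacked library 1 of the miR128KO ACC mice, left out by outcome, and were not redrawn with it. With it put back, the miR128KO count was 151, so chance is not excluded there. For the pooled fit, chance is excluded only among the libraries kept. For a difference of the ACC effect among genotypes, the real count was 0 and the highest other 4; all 60 splits reach a count of 0 by construction, so this decides nothing. At 1 h the real split gave 78 and the highest other 1, and within WT 338 and 0 (the real one, 1 of 10, in each), but 10 splits are too few for a share under 0.05.

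The thoracolumbar library of animal 3 at 1 h lacked the early response of animals 1 and 2, with Fos at 15.1 CPM against 317 and 384. A swap of the region labels within animal 3 is excluded, since its caudal Hox genes of groups 10 to 13 had a mean log2 CPM of 2.78, against 2.3 and 3.04 in the other thoracolumbar libraries and -1.16 and -2.31 in the other cervical ones. A library from another of these animals is excluded, since Ide lay 2.05 times above animals 1 and 2 and at 1.04 times its level in the cervical cord of animal 3. A cord that the ischemia did not reach cannot be told apart from a slower response: over genes raised at least 2-fold at 4 h, the median difference between regions was -0.101 in animal 3. The call counts without both libraries of this animal, 64 and 34, come from an exclusion chosen by outcome.

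Gabra2, mt-Nd3, Gm28438 and Ide stood at separate levels among the genotypes, and the WT Sham libraries spread over these levels. For Ide, an effect of the engineered microRNA loci is excluded, since it parted WT mice by 1.86 times at 4 h and 1.9 times at 1 h. For Gabra2, mt-Nd3 and Gm28438 it is not excluded: the WT Sham libraries differed by 3.24 times in Gabra2, but the library labelled WT Sham 3 lay within 1.3 times the miR128KO range in all 4 genes, so its label matters. Against a wrong label, Rnf169 (28.7 CPM), Tiparp (28.7), Samd10 (23.2) and Slc39a13 (32.1) lay there below all 4 miR128KO Sham libraries (at least 40.8, 42.5, 31 and 38). Of 14 genes that part miR128KO from WT without this library, 8 lay nearer miR128KO (57.1%). The rest, these 4 genes among them, lay nearer WT. Each miR128KO Sham library, left out the same way, gave 62.5% to 86.7%, and WT Sham libraries 1 and 2 gave 0 of 11 and 21 of 36. The share of 57.1% lies below the miR128KO Sham libraries by less than their spread, so it does not settle the label. A strain variant, such as the one that lowers Gabra2 in some C57BL/6J stocks, may also separate these mice. Gabra2 and mt-Nd3 lay on opposite sides of their midpoints in 22 of 23 libraries, but both were picked for parting the genotypes, so this does not decide between the explanations. WT Sham library 2 stood between the levels, with mt-Nd3 at 33.1 CPM, 0.516 of the way from the mean of miR155KI down to that of miR128KO, and a mixed sample cannot be told apart from a mouse with both mitochondrial types. Library 2 also stood apart from WT Sham library 1 in Gabra2 (123 against 50.1 CPM), mt-Nd3 (33.1 against 74.4) and Gm28438 (36.4 against 5.51). A wrong label of library 3 alone would not cover this. An effect of the engineered loci would need a mixed library 2 as well. These values argue against such an effect on the 3 genes, without excluding it. The lower Gabra2 in WT ACC may reflect mice of unequal background in the arms, whatever set that level, since its larger change in the other genotypes was 0.237 log2 units. Leaving out WT Sham libraries 2 and 3, which was chosen after the data were seen, left 1433 higher and 1018 lower genes at 4 h.

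Liver transcripts such as Hpx rose in ACC at 4 h, with Alb at 393, 131, 68.7 and 28.5 CPM in miR155KI ACC libraries 5 and 2, WT ACC library 2 and WT Sham library 3, and at up to 6.54 in the others. RNA from liver fits, since 96.9% of the counted hepatocyte genes (31 of 32) were highest in miR155KI ACC library 5. Genes that rise together from any source would also peak in the same library, so this does not settle the origin. A response shared by most ACC cords is excluded, since 3 of 11 ACC libraries had a hepatocyte score above the Sham bound. This count cannot exclude a response in single ACC cords. Adipocyte genes moved too: of 8 tested, 5 rose and 0 fell, and their origin was not tested. Whether the liver transcripts came from blood, from handling or from mixing of samples was not tested. Without the 4 libraries, 1857 of the 2914 calls were kept among 1991.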

How the results depend on the processing

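The exclusions of animal 3, of the libraries with Alb and of those with Gm28438, the unblocked fit of 18 libraries, the GABA and glycine list without Gabra2, and the fits of 1 h against 4 h without each 1 h library were chosen only after the results were seen; the other alternatives were fixed earlier. The cause was not tested except where fewer libraries or genes show it. At 1 h, 37 higher and 41 lower genes became 139 and 133 without a filter, 64 and 64 with DESeq2, 723 and 747 at an unadjusted p under 0.05, and 16 and 8 with at least a 2-fold change. Without both libraries of animal 3 the higher count was 64, and leaving out each library gave 16 to 88 higher and 18 to 54 lower. The block over the 1 h mice changed the calls of Hoxc10, Ctxn3 and Sgk1 and no other named gene or list. At 4 h, 1664 and 1250 became 2637 and 2514 at an unadjusted p, 142 and 16 with at least a 2-fold change, 1792 and 1269 with genotype as a covariate, 1487 to 1762 and 1089 to 1272 without each library, and 824 lower without the 4 libraries with Alb. Of 9 same-numbered pairs of 4 h mice, 1 had a correlation over 0.1 and 2 correlated best with their own number (range -0.221 to 0.19). Libraries of the same mouse at 1 h reached at most 0.0562 by this measure. It therefore cannot tell whether the 4 h numbers pair. With the replicate block over these 18 libraries, 1163 rose and 715 fell, against 1277 and 858 without it. Within miR128KO, library 1 put back gave 151 and DESeq2 874. Leaving out each library gave 170 to 324 in WT, 289 to 489 in miR128KO and 566 to 895 in miR155KI. The difference among genotypes stayed between 0 and 2, with 1 in DESeq2. The Sham test gave 31 without a filter, 82 with DESeq2 and 6 to 19 without each library. With an estimated correlation, the 9 lists past the threshold at 1 h became 0 and the 15 at 4 h became 4. The 1 h against 4 h correlation was 0.187 over genes of at least 1 log2 CPM. With library 1, the monocyte list was lost (adjusted p = 0.163), hypoxia was gained (adjusted p = 0.0271), and 3 lists passed with the chemokine index by r. At 1 h, S100a9 (range -0.41 to 1.1) and Ngp (-0.45 to 1.21) reversed without cervical library 1, from -0.04 and -0.01. Of 100 named 4 h genes past the threshold, 87 kept their call in every fit without a library, as did 18 of 30 at 1 h. Over the values of named genes and lists, DESeq2 left 215 as they were and made 3 stronger, its size factors left all 218, no filter left 204 and made 11 weaker and 3 stronger, genotype as a covariate left 154 and made 5 weaker, and library 1 put back left 152 and made 13 weaker and 4 stronger. Leaving out each library left 3096 as they were and made 168 weaker, 10 stronger and 2 reversed, the exclusion of the libraries with Alb left 104 and made 19 weaker, that of the 2 WT Sham libraries left 113 and made 10 weaker, and that of animal 3 left 83 and made 8 weaker and 4 stronger. The replicate block left 237 as they were and made 16 weaker and 1 stronger, and the unblocked fit of the same 18 libraries left 111 and made 12 weaker. With library 1, the 4 h calls of mt-Atp6 (adjusted p = 0.964), F13a1 (0.338), Lyz2 (0.269), Cd177 (0.249), Tsc22d3 (0.106), Olig2 (0.0767), Neu4 (0.0733), Hoxc6 (0.0699), Cxcl10 (0.0694), Nmur2 (0.0629), Kcns2 (0.0595) and Islr (0.0555) were lost. Without the 4 libraries with Alb, those of Olig2 (adjusted p = 0.163), Tsc22d3 (0.107), Neu4 (0.0799), Ccr1 (0.0704), Foxj1 (0.0701) and Siglech (0.0664) were lost, and so were others already lost without a single library. Under the block, whose numbers are not known to pair, Sgk1 (adjusted p = 0.0675), Kcnf1 (0.0652) and Gja1 (0.0553) had no call, which says nothing about the size of the effect. Among named genes without a call, a call was gained at 1 h without thoracolumbar library 3 by Egr1 (adjusted p = 1.62e-05), Jun (1.84e-05), Sgk1 (0.0047) and Olig2 (0.0206), without cervical library 1 by S100a9 (0.00707) and Ngp (0.0164), and without thoracolumbar library 1 by Prx (0.000115). At 4 h, Col1a2 gained one without miR155KI Sham library 1 (adjusted p = 0.0309) and in 3 other fits, and Ptgds without miR155KI Sham library 2 (adjusted p = 0.043). The floor of 3 counts, at 0.0908 to 0.192 CPM by library, limits the folds of genes near 0 in Sham, such as Ccl2, Ccl3 and Ccl4.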

Other observations

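The tests of the chemokine index against liver RNA and of Ide among WT mice were chosen only after the results were seen; the other tests in this part were fixed before their results. At 4 h, some genes of hypoxia, cholesterol synthesis and p53 passed. The prolyl hydroxylases P4ha1 (0.59, SE 0.0796) and P4ha2 (0.58, SE 0.0913), the glycolytic regulator Pfkfb3 (0.32, SE 0.0496) and adrenomedullin, Adm (0.60, SE 0.133), rose (n = 11 ACC and 11 Sham). Of 24 hypoxia genes, 6 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.0764). The sterol synthesis genes Hsd17b7 (0.28), Msmo1 (0.22) and Fdft1 (0.20) rose. Of 20 cholesterol genes, 8 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.00367, adjusted p = 0.65 with an estimated correlation). Fas (0.77, SE 0.142), Plk2 (0.49, SE 0.0568) and Mdm2 (0.29, SE 0.0437) rose and Trp53inp1 (-0.45, SE 0.0896) fell. Of 17 p53 targets, 5 rose and 1 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.296). Per1 (0.53) and Sgk1 (0.23) rose and Tsc22d3 (-0.28; adjusted p from 0.00184 to 0.107 over the 31 alternatives) fell; of 17 glucocorticoid response genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.221). Ifit1 rose by 0.61 (SE 0.130), and the rise of Irf1 (0.36) was lost in 14 of the 22 fits that left out a library (adjusted p = 0.0803 without WT ACC library 2). Of 17 interferon-stimulated genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.172).

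Few blood cell and support cell genes were called at 4 h, and in both directions. Csf3r, the growth factor receptor of neutrophils, fell by 0.46 log2 units (SE 0.109, adjusted p = 0.00355), and Lyz2 (-0.49, SE 0.118) and F13a1 (-0.56, SE 0.194) of monocytes fell. The call of F13a1 was lost in 13 of the 22 fits that left out a library (adjusted p = 0.0899 without miR128KO Sham library 3). With library 1 of the miR128KO ACC mice put back, the calls of both Lyz2 and F13a1 were lost (adjusted p from 0.000482 to 0.269 and from 0.0199 to 0.338 over the 31 alternatives). Of 12 neutrophil markers, 0 rose and 1 fell (0 and 8 adjusted over the list alone; camera adjusted p = 0.00602, adjusted p = 0.65 with an estimated correlation). Of 8 monocyte markers, 0 rose and 2 fell (0 and 2 adjusted over the list alone; camera adjusted p = 0.0337, adjusted p = 0.65 with an estimated correlation). Pdgfra (-0.29, SE 0.07), Neu4 (-0.49) and Cspg4 (-0.25) of oligodendrocyte precursors fell and Olig2 rose (0.48). The call of Cspg4 was lost in 4 of the 22 fits (adjusted p = 0.0576 without miR128KO Sham library 4). Those of Olig2 and Neu4 were lost with library 1 put back and without the 4 libraries with Alb (adjusted p from 0.00365 to 0.163 and from 0.00258 to 0.0799 over the 31 alternatives). Of 10 precursor markers, 1 rose and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.241). Ccdc153 fell by 0.555 and Fam183b by 0.39, and Foxj1 rose by 0.26 (adjusted p from 0.00756 to 0.0701 over the 31 alternatives). The call of Fam183b was lost in 16 of the 22 fits (adjusted p = 0.0864 without miR128KO Sham library 2). Of 9 ependymal markers, 1 rose and 2 fell (1 and 6 adjusted over the list alone; camera adjusted p = 0.0227, adjusted p = 0.603 with an estimated correlation). Of 9 red blood cell genes, 0 rose and 1 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.138).

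Position and mitochondrial genes at 4 h gave few calls. Hoxb8 fell by 0.27 (SE 0.0456), and Hoxd10 (-0.36) fell and Hoxc6 (0.29) rose with calls lost in 14 of the 22 fits each (adjusted p = 0.0847 without miR155KI Sham library 1, and 0.0791 without miR155KI ACC library 1). Of 17 caudal Hox genes, 0 rose and 2 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.0384, adjusted p = 0.603 with an estimated correlation), and of 10 rostral ones 1 rose and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.551). Of 13 mitochondrially encoded genes, 0 rose and 1 fell, mt-Atp6 at -0.52 with a call lost in 14 of the 22 fits (adjusted p = 0.078 without WT Sham library 3). In this list (0 and 0 adjusted over the list alone; camera adjusted p = 0.894) the median was -0.01, while the mean was 0.00 and the test pointed up. No call (0 and 0 over all genes, 0 and 0 adjusted over the list alone) was found among 12 oligodendrocyte (camera adjusted p = 0.221; Mbp 0.00), 12 endothelial (camera adjusted p = 0.797; Ly6c1 0.10, Flt1 0.11) and 9 pericyte and smooth muscle markers (camera adjusted p = 0.894; Rgs5 0.05, Vtn 0.03). The same holds for 4 lymphocyte (camera adjusted p = 0.411; Ighm -0.15, Trbc2 -0.69), 8 fibroblast and meningeal (camera adjusted p = 0.188; Ptgds 0.13, Col1a2 -0.47), 6 Schwann cell and dorsal root ganglion (camera adjusted p = 0.633; Prx -1.345) and 8 skeletal muscle genes (camera adjusted p = 0.554; Acta1 0.95, Mylpf 0.62).

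At 1 h, lists with a shift but no called member included homeostatic microglia (camera adjusted p = 5.61e-05 as lower, adjusted p = 0.939 with an estimated correlation; Csf1r -0.04; 0 and 0 of 17, 0 and 0 adjusted over the list alone) and endothelial markers (camera adjusted p = 0.00971 as lower, adjusted p = 0.939 with an estimated correlation; Flt1 -0.33, Slco1a4 0.05; 0 and 0 of 12, 0 and 0 adjusted over the list alone). Glucocorticoid response genes had a camera adjusted p of 0.044 as lower, with an adjusted p of 0.939 with an estimated correlation (0 and 0 of 17, 1 and 3 adjusted over the list alone; Mt1 -0.41). In that list Sgk1 had a value of -0.39 (adjusted p = 0.101), and passed with the mouse as a block (adjusted p = 0.0328; 6.88e-05 to 0.356 over the 11 alternatives). Lists with a member called at 1 h were glutamate signalling (1 higher, 0 lower of 35, 1 and 0 adjusted over the list alone; camera adjusted p = 0.354; Slc17a7), potassium channels (0 and 1 of 31, 1 and 3 adjusted over the list alone; camera adjusted p = 0.445; Kcna1) and reactive astrocyte genes (0 and 1 of 16, 0 and 2 adjusted over the list alone; camera adjusted p = 0.0708; Vim).

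No member was called at 1 h (0 and 0 over all genes) in the other lists. Adjusted over the list alone, the counts were also 0 and 0 for CXC, CX3C and XC ligands (camera adjusted p = 0.759; Cx3cl1 0.09, Cxcl14 -0.20), chemokine receptors (0.445; Cx3cr1 -0.18, Ackr1 0.12), hypoxia (0.759; Aldoa 0.04, Pgk1 0.09), unfolded protein and integrated stress response (0.69; Hspa5 0.10, Hsp90b1 0.02) and p53 targets (0.815; Zmat3 -0.00, Phlda3 0.03). The same holds for interferon-stimulated genes (0.0708; Stat2 0.03, Ifit2 -0.02), cholesterol synthesis (0.214; Hmgcs1 0.04), astrocytes (0.266; Slc1a2 -0.02, Aldoc -0.02), oligodendrocytes (0.0695; Mbp -0.15), fibroblasts and meninges (0.0643; Ptgds -0.08, Col1a2 0.18), ependyma (0.49; Foxj1 -0.03, Ccdc153 -0.01), Schwann cells and dorsal root ganglion (0.485; Prx 2.00) and skeletal muscle (0.417; Acta1 0.14, Mylpf 0.69). In 5 further lists with 0 and 0 the signs differed. Pericytes and smooth muscle (0.944; Rgs5 -0.10, Vtn -0.03) had a median of -0.03, a mean of 0.06 and a test pointing down. Neutrophils (0.445; S100a9 -0.04, Ngp -0.01) had a median of -0.04, a mean of -0.00 and a test pointing up. Monocytes (0.759; Fn1 -0.33, Lyz2 -0.06) had a median of -0.06, a mean of 0.13 and a test pointing up. Red blood cell genes (0.759; Bpgm -0.07, Hbb-bs -0.49) had a median of -0.12, a mean of -0.17 and a test pointing up. Lymphocytes (0.866; Ighm -0.18, Trbc2 0.07; 0 and 0) had a median of 0.07, a mean of 0.21 and a test pointing down. Adjusted over the list alone, the counts were 0 and 1 for cytokines and NF-kB feedback genes (0.417; Csf1 -0.17, Nfkbia -0.35), 2 and 0 for neurons (0.759; Snap25 -0.07, Nefm -0.19), 0 and 1 for oligodendrocyte precursors (0.848; Sox10 -0.01, Olig2 -0.37) and 2 and 1 for endothelial activation genes (0.655; Adamts4 0.00, Plat -0.09), whose median was -0.10, mean 0.01 and test down.

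A copy number gain at a segment of chromosome 19 may set apart the miR155KI mice and single WT mice. Some C57BL/6J stocks carry extra copies of Ide, Fgfbp3 and Btaf1. Ide stood at 104 ± 3.71 against 55.7 ± 4 CPM in Sham (SD, n = 4 each), and the prediction that its neighbours would follow was written before they were read. Fgfbp3 was 1.71 times and Btaf1 1.6 times as high in miR155KI Sham, with no overlap between the groups, which fits the gain. The higher level is no trait of the knock-in line alone: Ide stood at 106 CPM in WT Sham library 1 and at most at 57.2 in the other WT libraries of 4 h. At 1 h, WT animal 3 had 119 and 115 CPM, and animals 1 and 2 had at most 60.5. An effect of the engineered loci on Ide is thereby excluded (smaller ratio among WT mice 1.86), since 2 wrong labels would be needed. Fgfbp3 and Btaf1 were not compared among WT mice, and DNA was not measured.

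The chemokine index may follow other features of the ACC mice. With the hepatocyte score its r was 0.555 (permutation p = 0.0715), and with the immediate early gene score 0.282 (permutation p = 0.399, adjusted p = 0.851). Without the 2 libraries farthest from the median index, the latter r was 0.655 (permutation p = 0.0612, adjusted p = 0.205) and rho 0.75 (permutation p = 0.0258, adjusted p = 0.129). With library 1 put back, r was 0.809 (permutation p = 0.0138, adjusted p = 0.046) and rho 0.524 (permutation p = 0.0834, adjusted p = 0.278), of which only the r passed. In the 11 mice neither relation passed, and the immediate early one depends on which libraries are in.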
